A study of Bos taurus with 3 samples.

How the data were processed

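Argonaute HITS-CLIP (high-throughput sequencing of RNA isolated by crosslinking immunoprecipitation) was measured in dissected bovine retina. Per the labels' protocols, clusters of retinal cells were exposed to ultraviolet light, which links RNA to the proteins bound to it, and libraries were made from the RNA that co-purified with Argonaute, the protein that carries microRNAs (miRNAs) to their targets. The labels describe 3 samples, numbered as replicates 1 to 3 of 1 group, with no control sample. Nothing in the labels says that the replicates came from separate animals, so a p-value over replicates, or an SD with n = 3, may measure technical spread only.

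The submitters' processing notes name CASAVA 1.8.1 and GSNAP without giving their roles. The peak caller, the genome build and the rule that made a peak a listed site are not given in the sources used here. The deposited tables are 2 sheets, 1 for each strand, and each line pairs 1 gene name and 1 location class with the peak found in each of the 3 replicates. Per the file headers, the tags of a peak are a count of tags per replicate, and the values were whole numbers from 3 upwards with a different total in each replicate. Per the file headers, the −log10 of the p-value, multiplied by 10, is given for every peak; every peak reached 200.02 or more, and the highest value was 3100. Per the file headers, a fold enrichment is given for every peak as a ratio over a background that the headers do not describe. The authors' location class and gene name were taken as they stand. A site's coordinates are the outermost ends of its 3 peaks in the authors' coordinates, counted from 1.

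The height of a site is the mean of its tags in the 3 replicates, without scaling. The tags in the listed sites summed to 6421 in replicate 1, 5779 in replicate 2 and 4114 in replicate 3. These sums cover only the listed sites and are not the depths of the libraries. With a median of 12, 10 and 7 tags per site in the 3 replicates, a site's value carries a large counting error. Tags were not described as carrying molecular identifiers, so intervals cover counting error only. Whether tags with the same start were counted once is not given in the sources used here, so a tag count may be bounded by the length of its peak.

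Analyses ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Gene names were upper-cased, and 19 gene lists were written before the data were examined, as were the tests and most alternatives. The lists hold 545 entries; 6 of them were not found in the NCBI RefSeq gene table of assembly ARS-UCD2.0 and were left out. That table served for names only, and none of its coordinates were used. Of the 280 gene names in the files, 258 matched a symbol of the table, 9 matched a synonym and 13 matched none. Shares carry 95% Wilson intervals. Each list was compared with a list of genes of other tissues by Fisher's exact test (two-sided), with Benjamini-Hochberg adjustment over 18 lists. The height of a list's target genes, as mean log2 tags of the best site per gene, was compared with that of all other named genes, miRNA genes included. This was a two-sided permutation test with 100000 resamples, adjusted over the lists with at least 5 target genes. The strands were compared with an exact binomial test and a permutation test of medians. Correlations between replicates are across sites, which are not independent replicates. Permutation tests over sites treat the sites as independent, though sites of the same gene may not be. The spread of each site's tags over the 3 replicates was compared with counting noise by an exact multinomial test, with the replicates scaled by the median ratio over sites and Benjamini-Hochberg adjustment over all 402 sites; this test was added after the data were seen. In simulated data on 402 sites, the multinomial test called 39 of 50 sites changed 4-fold in 1 replicate, 9 of 50 changed 2-fold and 4 of 302 unchanged sites. In simulated lists of 12 genes drawn from the 280, the permutation test called 100 of 100 lists raised 2-fold and 8 of 100 unchanged lists. These calls were made without adjustment over lists and with fewer resamples, so the rates do not carry over to the adjusted calls. A 2-fold rise also exceeds the largest difference in the main test, 0.61 on the log2 scale.

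Genes named in the text are the 10 genes with the highest site, the 10 genes with the most sites, and of each list up to 4 target genes with the highest site, ties taken alphabetically; some genes that this rule selects are not reported here. Any other named gene was chosen after its values were seen, as were all miRNA genes. The alternatives were a height above the median, sites within 100 nt or 1000 nt merged, matching by synonym, each strand alone, each replicate left out, another control list, other scales of the height, and log2 values with a pseudocount of 1. Alternatives chosen after the data were seen were leaving out unnamed and mitochondrial sites or miRNA genes, leaving out sites without a location class, heights scaled to the replicate totals or replaced by the summit pile-up or the authors' p score, the members of all other lists as the control, and other scalings of the replicates. Matches of miRNA seeds to site sequences, location by overlap with an annotation, and sites per chromosome against gene density need a genome and annotation of the files' build and were not analysed here. Sites per miRNA family were not analysed because the files assign no miRNA to a site; sites that lie in miRNA genes are described in place of them.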

Results

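Argonaute-bound RNA was sequenced from bovine retina to find where miRNAs contact their targets. There were 3 replicates of 1 group and no control sample, so every comparison lies within the list of sites. Each of the 402 sites was a peak in all 3 replicates, and the tags in them numbered 6421, 5779 and 4114 in replicates 1, 2 and 3. The 3 peaks of a site shared at least 17 bases in all 402 sites, with a median spread of 9 nt between their summits. Values per site are tags as mean ± SD over the replicates (n = 3), and coordinates are in the authors' build, whose name is not given in the sources used here.

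The question of the series was which transcripts carry miRNA target sites in the retina. Sites lay in 280 named genes, of which 22 were miRNA genes, and a further 32 sites carried no gene name. The tallest named sites were in MALAT1, a nuclear non-coding RNA, and GNAT1, which encodes the rod transducin alpha subunit. MALAT1 had a site of 64 ± 4.58 tags on chromosome 29 (45344020 to 45344138), and GNAT1 had one of 60 ± 21.7 tags in its 3' UTR on chromosome 22 (50877454 to 50877801). The summit pile-up of the MALAT1 site was 20, 20 and 18 in the 3 replicates, at or near the highest in any peak, 20. Other phototransduction genes were among the 10 with the tallest sites. PDE6G, the inhibitory subunit of rod phosphodiesterase, had a 3' UTR site of 43 ± 10.1 tags on chromosome 19 (52243300 to 52243643). RGS9BP, which anchors the complex that switches transducin off, had a 3' UTR site of 35.3 ± 12 tags on chromosome 18 (42137920 to 42138051).

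The other genes among the 10 with the tallest sites were of mixed function. The non-coding transcript that the authors name as the homolog of mouse 2900097C17Rik had a site of 52.3 ± 39.6 tags on chromosome 13 (65758368 to 65758941), with 98 tags in replicate 2 and 28 and 31 in the others. CMTM4 had a 3' UTR site of 44.3 ± 3.21 tags on chromosome 18 (33248848 to 33248999). MAP1B, a microtubule-associated protein of neurons, had a 3' UTR site of 39.7 ± 8.33 tags on chromosome 20 (10101390 to 10101558). MBNL2, a splicing regulator, had a 5' UTR site of 35.3 ± 17.6 tags on chromosome 12 (71803470 to 71803703). CAMTA2, a calmodulin-binding transcription activator, had a 3' UTR site of 33.7 ± 7.09 tags on chromosome 19 (26629858 to 26630258). RBP3, the retinoid carrier of the interphotoreceptor matrix, had a coding site of 34.7 ± 33.8 tags on chromosome 28 (42010451 to 42010829), which rested on replicate 2: its tags were 6, 72 and 26 in the 3 replicates.

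**Figure D1:**
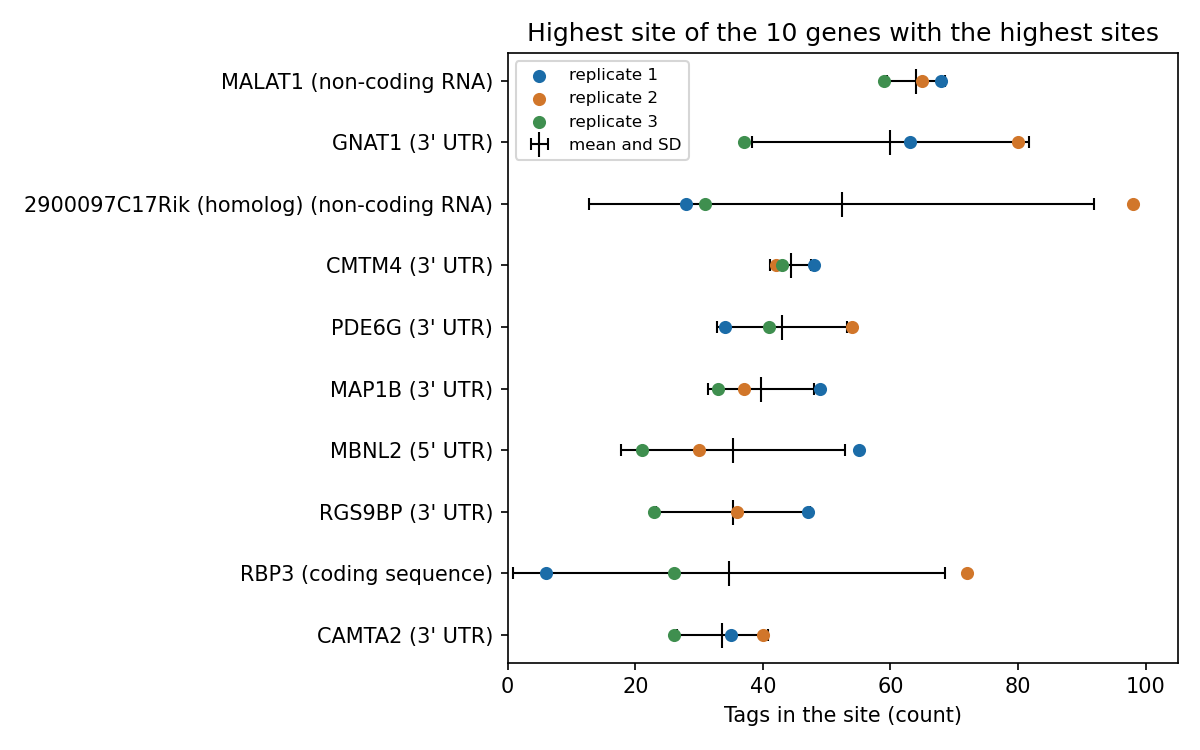
Tags (count, horizontal axis) in the highest site of each of the 10 genes with the tallest named sites; points are replicates 1 to 3, and the vertical tick with its bar is the mean and SD. The SD is 4.58 tags for MALAT1 and 3.21 for CMTM4, while RBP3 spans 6 to 72 tags.

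Most named genes carried a single site, as did each of the 22 miRNA genes among them. Of the 280 genes, 50 had 2 or more sites (17.9%, 95% Wilson interval 13.8 to 22.8), and these 50 held 140 sites. MAP1B and SAG, the rod arrestin, had 7 sites each, with 127 ± 26.8 and 68.3 ± 10.8 tags per gene (n = 3). The 2900097C17Rik homolog had 6 sites and 145 ± 70.3 tags. There were 5 sites each in GNAT1, in GNB1 (the rod transducin beta subunit), in TNPO1 (a nuclear import receptor) and in TNRC6B (an Argonaute partner in silencing). HIPK3, a protein kinase, IMPG2, a proteoglycan of the interphotoreceptor matrix, and RBP3 had 4 each. In TNPO1 all 5 sites lay in the 3' UTR, while 6 of the 7 SAG sites and 4 of the 5 GNB1 sites lay in coding sequence. The number of genes with 2 or more sites was 26 when only sites above the median height entered, and 36 with sites within 1000 nt merged.

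The lists fixed beforehand ask which groups of retinal genes were targets. Phototransduction genes led: 13 of 33 members carried a site (39.4%, Wilson interval 24.7 to 56.3), against 0 of 36 genes of other tissues, with a Wilson upper bound of 9.64% (Fisher's exact test, adjusted p = 0.000267). The photoreceptor structure and transcription list followed with 10 of 31 (32.3%, interval 18.6 to 49.9, Fisher's exact test, adjusted p = 0.00161). With 0 targets in the control list, each of these tests rests on the list's own count and the size of the control. Genes of other tissues may have little mRNA in the retina, so few sites among them would be likely in any case. The mRNA levels were not measured, so these shares do not show that photoreceptor transcripts were bound more than their abundance would give. Against the members of all other lists, a comparison chosen after the data were seen, the shares were 39.4% against 8.02% and 32.3% against 8.61% (Fisher's exact test, adjusted p = 5.31e-05 and 0.00337), and no other list passed the test. The tallest phototransduction sites included those of GNAT1, PDE6G and RGS9BP. In the structural list, CEP290, a protein of the connecting cilium, had an intron site of 26.7 ± 11.7 tags on chromosome 5 (20298231 to 20298375). PRPH2, a protein of outer segment disc rims, had a 3' UTR site of 16.7 ± 8.33 tags on chromosome 23 (16870074 to 16870268). RP1, a protein of the photoreceptor axoneme, had a 3' UTR site of 13.7 ± 9.87 tags, with 7, 9 and 25 in the 3 replicates, and ROM1, a partner of PRPH2, had a coding site of 12.3 ± 4.73 tags. PRCD, a disc protein with a site of 9.67 ± 2.52 tags, is on the list and was left out of its count because the gene table lacks the name.

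**Figure D2:**
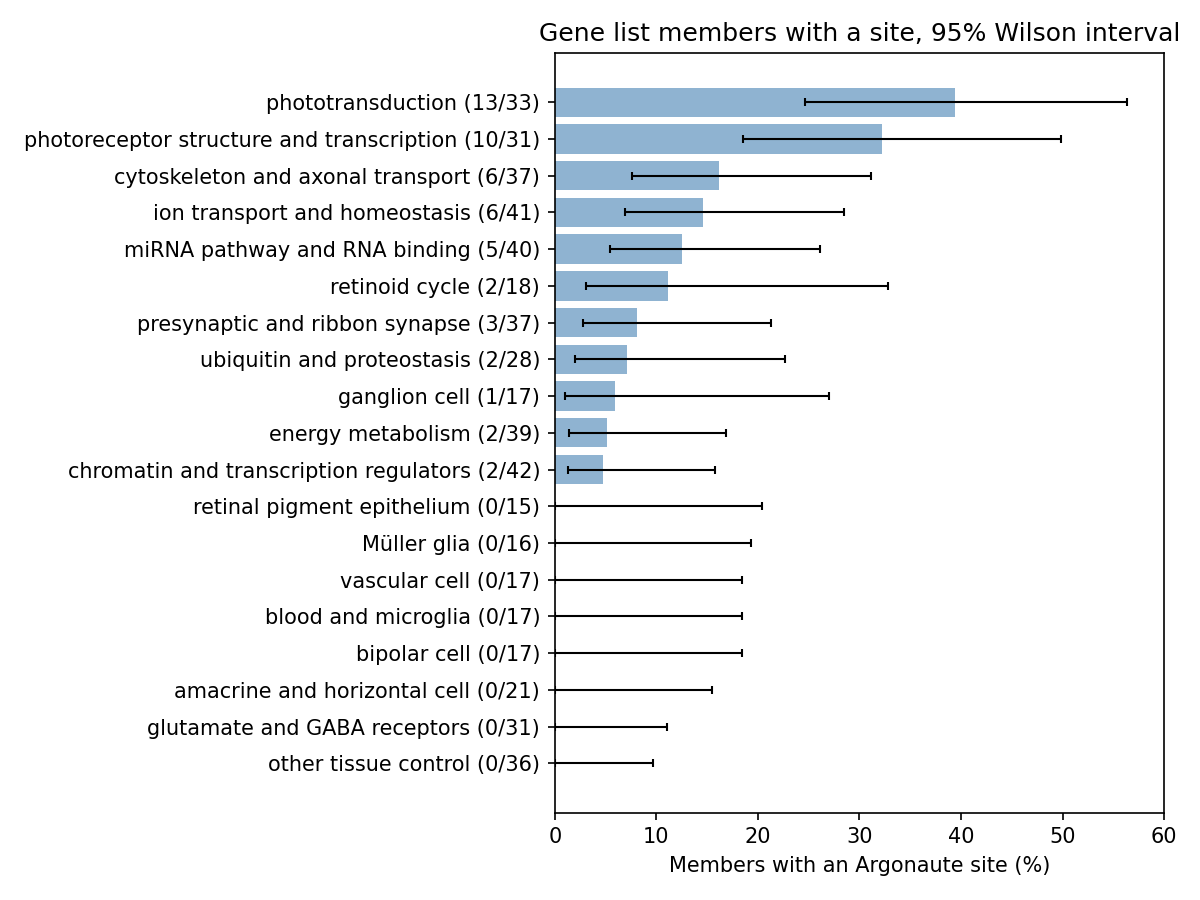
Share of each gene list's members that carried a site (%, horizontal axis), with targets and members in brackets; bars are shares and lines 95% Wilson intervals. Phototransduction (13 of 33) and photoreceptor structure and transcription (10 of 31) reach the highest shares, and 8 lists, the other tissue control among them, hold no target.

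The remaining lists did not pass the test against the control list, with adjusted p from 0.122 to 1 (Fisher's exact test). The cytoskeleton and axonal transport list held 6 targets of 37: MAP1B, KIF1B, a kinesin motor, with an intron site of 19.3 ± 17 tags, ACTG1, the cytoplasmic gamma actin, with 14.7 ± 1.53, and MAP2, a dendritic microtubule protein, with 8.67 ± 3.79 in its best site were the tallest. The ion transport list held 6 of 41, among them the bicarbonate transporter SLC4A7 with 28.3 ± 8.50 tags, the sodium pump beta subunit ATP1B2 with 20.3 ± 7.23 and the potassium channel subunit KCNV2 with 11 ± 2.65. Of the miRNA pathway and RNA binding list 5 of 40 were targets, among them MBNL2, HNRNPU with 20.3 ± 8.62 tags, TNRC6B with 14.3 ± 8.50 and the splicing regulator CELF2 with 11 ± 5.29. The retinoid cycle list held 2 of 18, RBP3 and the retinol dehydrogenase RDH10 with 17 ± 2.65 tags.

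Few genes of synapses, metabolism, protein turnover or chromatin were listed. The presynaptic list held 3 of 37, the calcium channel subunit CACNA1F with 9 ± 4.36 tags, VAMP2 with 7.67 ± 1.15 and SYT1 with 7 ± 3.61. The glutamate and GABA receptor list held 0 of 31 (Wilson upper bound 11%). Energy metabolism held 2 of 39, GOT2 with 16 ± 10.1 tags and GAPDH with 7.67 ± 0.577. Ubiquitin and proteostasis held 2 of 28, the chaperones HSP90AA1 with 10 ± 1.73 and HSPA8 with 7 ± 3.46. Chromatin and transcription regulators held 2 of 42, TET2, an enzyme that oxidises methylcytosine, with 11.7 ± 3.51 and the remodeller CHD7 with 8.33 ± 3.06.

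Markers of the other cell types a dissected retina can hold were nearly absent from the list. Of 17 ganglion cell markers 1 was a target, UCHL1, with 9.33 ± 3.21 tags. None of 16 Müller glia, 17 bipolar cell, 21 amacrine and horizontal cell, 15 retinal pigment epithelium, 17 blood and microglia and 17 vascular cell markers carried a site, with Wilson upper bounds between 15.5% and 20.4%. A gene without a listed site is not shown to be unbound, since the list holds only peaks past the authors' threshold. The mRNA levels of these markers were not measured, so a low share may also reflect scarce transcripts. With the plus-strand table alone neither photoreceptor list passed the test, at 18.2% for phototransduction and 9.68% for the structural list (adjusted p = 0.166 and 0.533, Fisher's exact test). With the minus-strand table alone both did, at 21.2% and 22.6% in the same order (adjusted p = 0.0356 for both, Fisher's exact test). Members with sites only on the strand left out count as having none. With sites above the median height the structural list did not pass (Fisher's exact test, adjusted p = 0.158). With vascular, blood and microglia genes added, the control held 0 targets of 70 in place of 36, which lowers p by construction, and 5 lists passed the test; the cytoskeleton, ion transport and miRNA pathway lists, which this added, did not pass against the members of all other lists (Fisher's exact test, adjusted p = 0.577, 0.577 and 0.748).

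The heights of these groups were compared among the 280 named genes, which include the 22 miRNA genes. Of the 5 lists with at least 5 target genes, the phototransduction genes had the tallest best sites, at 4.06 ± 0.97 mean log2 tags over 13 genes. The other 267 named genes had 3.44 ± 0.74, a difference of 0.61 (permutation test, adjusted p = 0.0223). With the miRNA genes left out, a setting chosen after the data were seen, the difference was 0.58 (permutation test, adjusted p = 0.0403). The best of several sites tends to be taller than a single one. Phototransduction genes had 2.46 ± 1.98 sites per gene, against 1.29 ± 0.80 in other genes outside miRNA genes. The difference in best sites may therefore partly reflect the number of sites, and mRNA levels were not measured. The other 4 lists tested did not pass the test. The miRNA pathway genes lay 0.55 above the other genes (permutation test, adjusted p = 0.262) and the cytoskeleton genes 0.23 above them (permutation test, adjusted p = 0.797). The photoreceptor structure genes had a difference of -0.05 and the ion transport genes one of -0.01 (permutation test, adjusted p = 0.986 for both). The phototransduction call of the permutation test was lost without replicate 2 (difference 0.49, adjusted p = 0.128), with ranks (adjusted p = 0.0798), with every site on its own (difference 0.21, adjusted p = 0.483), with the summit pile-up as the height (difference 0.36, adjusted p = 0.0940) and among sites above the median height (difference 0.31, adjusted p = 0.221). With the minus strand alone, which left 7 of the 13 genes, the difference was 0.62 and the call was lost as well (permutation test, adjusted p = 0.0696).

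The authors' location classes show where in the transcripts Argonaute was found. The 3' UTR held 223 of the 402 sites (55.5%, Wilson interval 50.6 to 60.3) in 180 genes, and 55.1% ± 3.17 of the tags (n = 3). Coding sequence held 81 sites (20.1%, interval 16.5 to 24.3), introns 34 (8.46%, interval 6.12 to 11.6) and non-coding RNAs 30 (7.46%, interval 5.28 to 10.5). There were 2 sites in 5' UTRs, in MBNL2 and in NRL, the rod transcription factor, and 1 between genes, while 31 sites had no class. Coding sites were lower than 3' UTR sites, at 3.26 ± 0.58 against 3.57 ± 0.72 mean log2 tags (permutation test, adjusted p = 0.00192). Intron sites were lower as well, at 3.16 ± 0.72 (permutation test, adjusted p = 0.00375), and sites in non-coding RNAs were at 3.55 ± 0.97 (permutation test, adjusted p = 0.907). These tests took sites as independent, though some genes held several. Among sites above the median height the 3' UTR share was 64.3%, the coding share 14.3% and the intron share 5.10%.

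**Figure D3:**
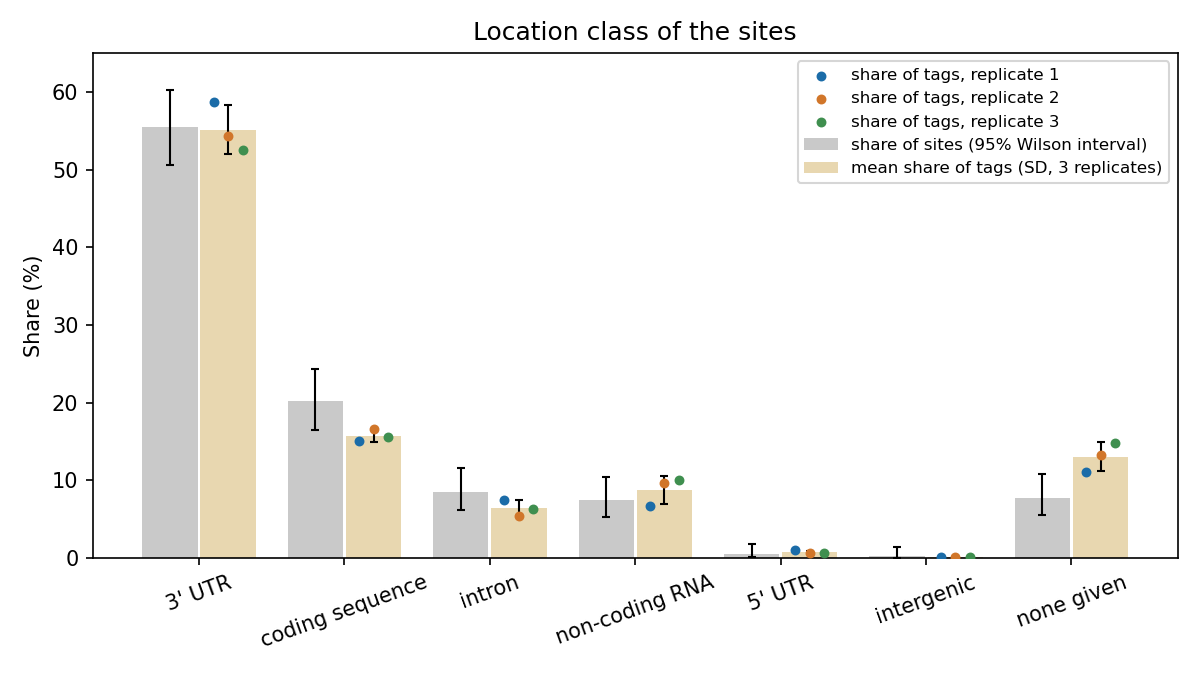
Share of sites (grey bars, 95% Wilson interval) and share of tags (tan bars, mean and SD of 3 replicates, points for each replicate) by the authors' location class; the vertical axis is in percent. The 3' UTR takes 55.5% of sites, and sites with no class take 7.71% of sites and 13% of tags.

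Of the 22 sites in miRNA genes, the tallest were in MIR182 and MIR183, which form a cluster with MIR96 on chromosome 4 (96328730 to 96333518) and are abundant in photoreceptors. MIR182 had 16.3 ± 1.53 tags, MIR183 12.7 ± 1.15 and MIR96 10 ± 1.73. Members of the MIR30 family were listed at 5 genes: MIR30E with 11.3 ± 0.577 tags, MIR30A with 11 in every replicate, MIR30D with 9.33 ± 0.577, MIR30C with 8.67 ± 2.08 and MIR30F with 6.67 ± 1.15. These miRNAs have closely related sequences, so the authors' alignment could assign a tag of 1 member to another. MIR204, MIR211 and MIR181C had 9 ± 2, 6 in every replicate and 6.67 ± 2.08 tags. MIR451, a miRNA of red blood cells, had 9 ± 1 tags, whereas no blood or microglia marker gene carried a site. A peak's length bounded its tags, as described below, and the share of the allowed number that was reached differed between these sites. Averaged over the replicates, it ran from 15.9% in MIR181C to 96.7% in MIR451, and was 33.8% in MIR182. Its mean was 48.6% in miRNA gene sites against 26.5% in other sites. The ranking of these sites, and equal tags in every replicate, may therefore partly reflect peak length. The files assign no miRNA to the sites in other genes.

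The strand tables were compared as a check of their yield. The plus strand held 189 sites, or 47% (Wilson interval 42.2 to 51.9, exact binomial test, p = 0.251). The median height was 10.7 tags on the plus strand and 9.33 on the minus strand (permutation test, p = 0.0985), and the median length 79.3 and 65.7 nt (permutation test, p = 0.000750). Of the 30 sites in non-coding RNAs, 27 lay on the minus strand (Fisher's exact test, adjusted p = 8.75e-05), and 21 of the 22 miRNA genes did. As a difference in mean log2 tags the height differed by 0.19 between the strands (permutation test, p = 0.0138).

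Replicates 2 and 3 were the most alike across the 402 sites, with a Pearson correlation of 0.861 and a Spearman correlation of 0.647. Replicates 1 and 2 gave 0.699 and 0.561, and replicates 1 and 3 gave 0.690 and 0.452, in the same order. Tags at 20 sites, 4 of them unnamed, were spread over the replicates beyond counting noise (exact multinomial test with Benjamini-Hochberg adjustment), with the highest scaled value in replicate 1 at 8 sites, in replicate 2 at 7 and in replicate 3 at 5. With the replicates scaled by the fold enrichment steps 24 sites passed the exact test, 13 of them among the 20, and the highest value lay in replicate 1 at 1 site, in replicate 2 at 7 and in replicate 3 at 16. The RBP3 coding site had the smallest adjusted p of a named site, 1.44e-14. By the same exact test it was followed by the tallest site of the 2900097C17Rik homolog (adjusted p = 2.61e-10), by the second MALAT1 site, with 42, 76 and 69 tags (adjusted p = 9.23e-05), and by the RP1 3' UTR site (adjusted p = 0.000402). Sites lower in replicate 2 than in replicate 1 included KIF1B, with 39, 10 and 9 tags (exact multinomial test, adjusted p = 0.00472). The fold enrichment steps ended this call (exact multinomial test, adjusted p = 0.0657). The tags of a site were counted over peaks whose length differed between replicates, and the exact test took no account of it. The peaks of this RBP3 site were 46, 376 and 183 nt long in replicates 1 to 3. Those of the homolog's tallest site were 123, 535 and 239 nt long. In both, the longest peak held the most tags, while at the second MALAT1 site it did not. Some calls may therefore partly reflect the extent of the peaks, which was not tested.

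The number of tags in a peak was bounded by its length. In all 1206 peaks the length exceeded the tag count by at least 19 nt, and 45 peaks met that bound exactly. When tags were shuffled over the peaks of a replicate a median of 114 peaks passed it. Peaks with more tags tended to be longer, so the shuffle would be likely to break such a bound whatever its source. The highest pile-up at a summit, taken from the fold enrichment column, was 20 in each replicate and was reached in 10 peaks. Whether tags with the same start were counted once is not given in the sources used here. Free counting of repeated starts would let short peaks pass the bound, which none did, so these limits argue against it. Tags of 20 nt counted once per start would give both limits. If so, a tag count is a number of distinct start positions, and sites near the bound would be compressed most, tall ones as well as short ones. The summit pile-up of the MALAT1 site would then lie at or near its limit. The tags of the MALAT1 site were 68%, 69.1% and 67.0% of the number that the bound allows in the 3 replicates, and the MIR211 peak in replicate 3 held 6 tags in 25 nt.

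**Figure D4:**
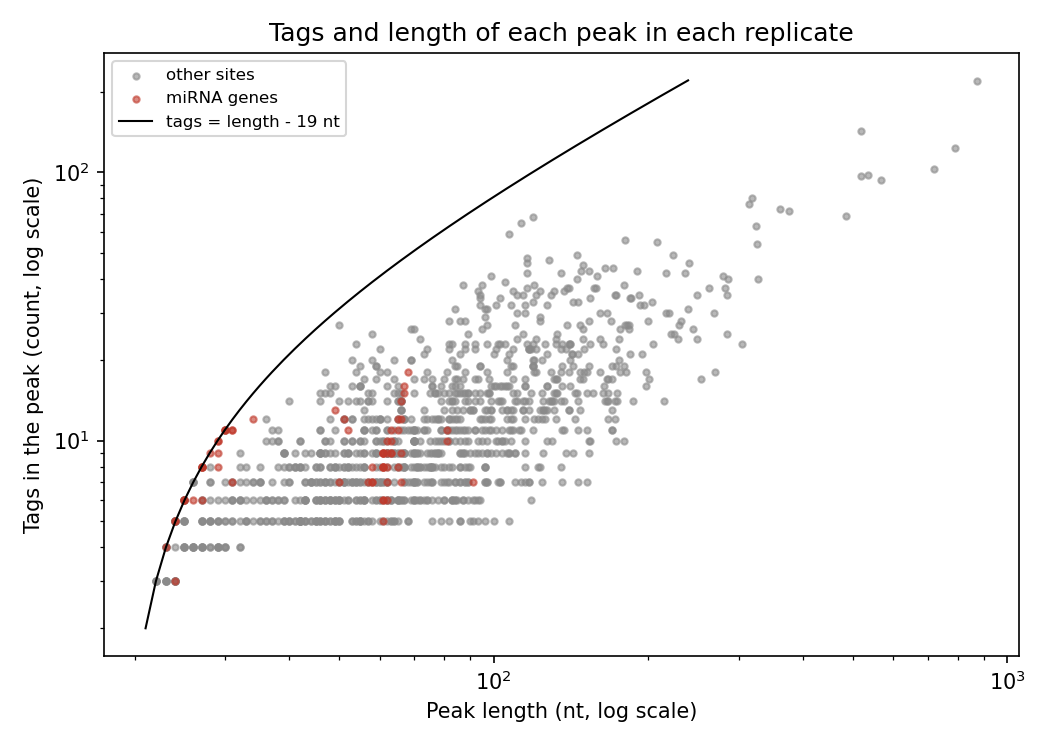
Tags (count, log axis) against length (nt, log axis) of all 1206 peaks, 3 for each site, with miRNA gene sites in red; the line marks a tag count 19 below the length. No peak lies above the line, and 45 lie on it.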

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

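All tests in this part were chosen after the data were seen. The sites without a gene name enter no comparison between genes, yet they include the sites with the most tags. They were 32, with 13.2% ± 1.92 of the tags (n = 3). The tallest site of all had 153 ± 61.6 tags, on the unplaced sequence JH126334 (13078 to 13950). Its tags were 97, 219 and 143 in the 3 replicates, a spread beyond counting noise (exact multinomial test, adjusted p = 1.44e-14). The lengths of its peaks differed between replicates as well, which the test did not consider. Of the 32 unnamed sites, 11 lay on the mitochondrial chromosome, 10 of them on the plus strand, and these 11 took 6.23% ± 0.458 of the tags. The tallest of these had 87.7 ± 45.0 tags between positions 432 and 1357. There was no control sample, so these values were not compared with a control. The background behind the authors' fold enrichment is not described.

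The fold enrichment column, which gave neither the height nor the scaling of any main comparison, takes values that are whole multiples of 1 step per replicate and strand, to within 0.01 of a step. Read as the number of tags at the summit, its highest value was 20 in each replicate. On the plus strand the step was 1.32 times as large in replicate 2 and 2.07 times as large in replicate 3 as in replicate 1, while the tags in the listed sites were 87.9% and 65.6% of those in replicate 1. On the minus strand the steps were 1.36 and 2.38 times as large and the tags 92.3% and 62.4%.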

How the results depend on the processing

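Alternatives chosen after the data were seen are those that leave out unnamed and mitochondrial sites, miRNA genes or sites without a location class, the summit pile-up, p score and scaled heights, the members of all other lists as the control, and the other scalings of the replicates; the rest were planned. Keeping only sites above the median height left 196 sites, 136 genes and 26 genes with 2 or more sites, fewer by construction, and the plus strand share became 51.5% (exact binomial test, p = 0.721; main share 47.0%), the 3' UTR share 64.3%, the number of lists that differed from the control 1 in place of 2, and the number of lists that differed in height 0 in place of 1. The strands alone gave 24 (plus) and 26 (minus) genes with 2 or more sites, and 0 lists that differed from the control on the plus strand and 0 that differed in height on the minus strand, with fewer genes tested. With the larger control list, which also held 0 targets and so lowers p by construction, 5 lists differed. No list differed in height with ranks (0), with every site on its own (0) or with the summit pile-up (0), and leaving out each replicate in turn gave 0 to 1 lists, 0 without replicate 2. For the named lists without a call in height, the difference changed sign for ion transport with log2(height + 1) (0.00078), the sum of sites (0.034), every site on its own (0.19) and when replicates were left out (-0.088 to 0.063, above 0 without replicate 1 or 3), and for photoreceptor structure with the sum of sites (0.14) and the minus strand alone (0.0064). The strand difference in height passed the threshold as mean log2 tags (0.19). The 3' UTR share of named nuclear sites was 60.3%. Replicate correlations on log2(tags + 1) were 0.585 for replicates 1 and 3 and 0.761 for replicates 2 and 3, and r fell to 0.603 for replicates 1 and 2 in named nuclear sites. The cause was not tested where none is given.

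Merging sites, matching synonyms and the other settings kept the direction and side of the threshold of the results they were run on, except for the sites that differed between replicates. The number of sites that differed between replicates was 20 with tag totals, all 20 shared with the main scaling, and 17 in named nuclear sites. With the fold enrichment steps it was 24, of which 13 were shared, 7 calls were lost and 11 were added. Leaving out a replicate cannot change which sites are listed, since each is a peak in all 3, and for correlations it leaves the other pair. Seed matches, overlap with annotated regions, sites per chromosome and sites per miRNA family were not run. The values of single lists and location classes, and the plus strand share above the median height, were counted as well. Of these, 130 kept their direction and side of the threshold or stayed within their spread, 9 lost a call, 3 gained one and 4 moved. A further 7, all without a call, changed sign. Medians of 7 to 12 tags per site limit what a single site can show. No paired analysis was possible because there is 1 group.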

Other observations

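All tests in this part were chosen after the data were seen. Phototransduction transcripts differed from other targets in where their sites lay. Of their 32 sites, 24 were in coding sequence (75.0%, Wilson interval 57.9 to 86.7) and 7 in the 3' UTR, against 57 coding and 216 3' UTR sites among the 316 sites of other genes outside miRNA genes. Of the 13 genes, 10 had at least 1 coding site: these included both sites of PDE6A, a catalytic subunit of rod phosphodiesterase, both sites of PDC, the transducin-binding phosphoprotein phosducin, and the single sites of CNGA1, a rod channel subunit, ARR3, the cone arrestin, and GNB3, the cone transducin beta subunit. They also carried more sites per gene, 2.46 ± 1.98 against 1.29 ± 0.80 (permutation test, adjusted p = 0.00440). The photoreceptor structure genes had 6 coding sites of 16 (37.5%), and the test did not separate them from other genes (permutation test over genes, adjusted p = 0.641).

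Pooled after their shares were seen, and so without a test, the phototransduction and photoreceptor structure lists held 23 targets of 64, against 1 of 70 markers of bipolar, amacrine, horizontal and ganglion cells and Müller glia, 0 of 15 pigment epithelium markers, 0 of 34 blood, microglia and vascular markers and 3 of 68 synapse and receptor genes. Outside the lists, ELOVL4, a fatty acid elongase, had a site of 26.3 ± 9.02 tags and C2ORF71, a photoreceptor cilium protein, one of 25.7 ± 17.6, with 46, 15 and 16 tags in the 3 replicates. Among the 8 genes with 3 sites were XIAP, an inhibitor of apoptosis, with 56.7 ± 15.7 tags over its sites, and PPP3R1, the calcineurin regulatory subunit, with 52.7 ± 25.7.

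The excess of coding sites in phototransduction genes was 51.0 percentage points in the mean share per gene (permutation test, adjusted p = 0.0001), and between 48.4 and 56.7 points when each of the 13 genes was left out in turn. Genes with several sites may reach the coding sequence more often, but against genes in the same class of 1, 2 or 3 or more sites the difference was 50.7 points, and against genes with exactly as many sites 51.3 points (permutation test, p = 3e-05 for both). An mRNA with many tags could show weaker coding sites too, but against genes in the same 1 of 5 classes of tags per gene the difference was 53.0 points (permutation test, p = 3e-05); tags stand in for mRNA level here, which was not measured. Within the list, coding sites were lower than 3' UTR sites by 0.90 on the log2 scale (24 and 7 sites, permutation test, p = 0.00727). That test shuffled sites without regard to gene, so sites of the same gene count as independent and its p may be too small. Among genes with a single site the excess of coding sites was 32.2 points with 6 genes (permutation test, p = 0.0811). The length of the 3' UTRs and mRNA levels remain open, and no biological explanation was tested.

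The miRNA genes lay almost all on the minus strand, 21 against 1 (exact binomial test, p = 1.10e-05). Several sites of 1 cluster could repeat a strand, but with sites within 100 kb joined 14 loci against 1 remained (exact binomial test, p = 0.000977). The plus-strand table holds 11 unnamed nuclear sites, and counting all of these as miRNA genes, and none of the 10 on the minus strand, would give 12 against 21 (exact binomial test, p = 0.163). That is the most they could add, since they span up to 873 nt and miRNA gene sites 27 to 91 nt: the 5 of at most 91 nt would give 6 against 21 (exact binomial test, p = 0.00592), and all unnamed nuclear sites of both strands 12 against 31 (exact binomial test, p = 0.00540). How long a site of an unnamed miRNA gene would be is not known, so it cannot be told apart whether miRNA genes of the plus strand were left without a name, since the files give no sequence; a difference in how the authors filtered or named the strand tables is also open, and no biological explanation was tested.

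Sites of 1 gene deviated together between replicates. In C1H21ORF91, for example, all 3 sites were highest in replicate 2, with 31, 83 and 17 tags per gene. Over the 50 genes with 2 or more sites, 46.7% of the deviation between replicates lay between genes, against a median of 35.2% when sites were shuffled over genes, which argues against counting noise (permutation test, p = 0.00453). A broad stretch of tags split into neighbouring sites could produce this, but with only sites over 500 nt apart the permutation p was 0.00259, and shuffling within the location class gave p = 0.00543. The pattern rests on few genes: without C1H21ORF91, RP1 and RBP3, picked because they weighed most, p was 0.227. Differences between the animals or preparations behind the replicates may be the source for those genes, which the labels do not allow to be tested. The tags were counted over peaks whose length differed between replicates, and the test took no account of it. In C1H21ORF91 the 3 peaks were 58, 84 and 92 nt long in replicate 1 and 284, 216 and 161 nt in replicate 2. In replicate 3 they were 37, 62 and 74 nt, so the extent of the peaks is open as well.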
